A study of Arabidopsis thaliana with 8 samples.

How the data were processed

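Endosperm of Arabidopsis thaliana seeds was collected by laser capture microdissection at 6 days after pollination from 4 crosses between the Col-0 wild type and the ethylene-insensitive mutant ein2-5, with 2 libraries per cross and 8 in all. Total RNA was extracted with a micro-scale RNA kit and libraries were made with a NEBNext Ultra kit, per the labels. The labels do not state whether the library protocol kept strand information, so transcripts of overlapping genes on opposite strands cannot be separated. The labels name the maternal parent as the emasculated one but do not say which name of a cross is the mother, and the parent written before the x was taken as the mother.

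The deposited table gives FPKM (fragments scaled by transcript length and by mapped fragments in the library), computed by the authors, for 34133 genes in 8 columns, of which 0 were left unused. Alignment and quantification used TopHat2 2.1.1, SAMtools 1.5 and Cufflinks 2.2.1 with the TAIR10 genome, per the submitters' processing notes. Their options and filters are not given. FPKM values summed to between 965922 and 1068714 per library, so no rescaling to a common total was visible. Gene symbols and transcript lengths came from the TAIR10.1 reference annotation, which matched 31416 of the identifiers. It was used for names and lengths alone, and no coordinates are printed because the 2 assemblies may differ.

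No read counts accompany the FPKM values in the table. The relative depth of each library was estimated from genes with a single annotated transcript that are listed at low FPKM in only a few libraries. The smallest values of such genes step in units of a single fragment. Among 4107 low values, 98.3% were whole multiples of that unit within 0.06 of a fragment, against 12% by chance. A length correction of 340 nt fitted these steps best in transcripts of at least 1.5 kb. Relative depth was estimated at 0.535 to 1.616, a 3.02-fold range, and 1 fragment corresponded to 0.45 to 1.35 FPKM on a transcript of 1.5 kb. These depths are estimates, and they cover counting error alone. Fragments per gene were estimated with a floor on the corrected length, which overstates them for transcripts shorter than the correction.

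Values were analysed as log2(FPKM + 1), so fold changes are understated for genes near 1 FPKM. Genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 19719 genes. Another 11790 genes were at 0 in every library. Group means of the 4 crosses were fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a variance trend, two-sided), with all 8 libraries sharing the estimate of spread. This left 4 residual degrees of freedom, to which the moderation added 3.72. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. There were 7 comparisons: 4 between crosses, the maternal and the paternal ein2-5 effect, each averaged over the genotype of the other parent, and their interaction, which is the change from a mutant father with a mutant mother minus that with a wild-type mother. Comparisons that share libraries share their chance values. The labels do not say whether replicate libraries came from separate plants or captured regions of the same ones, so p-values measure the spread between these samples.

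There were 19 gene lists, with 302 different genes, fixed before the data were examined together with the comparisons, the tests, the threshold and the first set of other settings. They cover ethylene perception and signalling, ethylene-responsive genes, ethylene biosynthesis, imprinted genes and PRC2 (a chromatin repressor complex), type I MADS-box genes, seed size regulators, auxin biosynthesis and Aux/IAA genes, abscisic acid, cell cycle and cytokinesis, DNA replication, DNA methylation and demethylation, defence and jasmonate response, heat shock proteins, photosynthesis, seed storage proteins and oleosins, sugar transport and cleavage, and markers of endosperm, seed coat and embryo. Each list was compared with all other tested genes by limma's camera test with a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with adjustment over the 19 lists. A list score is the mean log2(FPKM + 1) of its tested members in a library minus the mean of that value over the 8 libraries. Members were also tested gene by gene, adjusted over all genes and over the list alone.

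The genes named in a comparison of crosses were chosen by a rule fixed in advance. It takes up to 10 genes per direction with the largest change among those called without overlap between libraries, filled to 5 by the smallest unadjusted p where fewer passed, EIN2 always, and from each list up to 4 called members or else the member with the highest mean FPKM. The averaged parental effects and the interaction use the rule without the fill. Any other gene is said to have been chosen after its values were seen. Several lists hold close paralogs, among them PHE1 and PHE2, the chlorophyll-binding CAB genes, the RuBisCO small subunit genes and the albumin genes, and how fragments shared between them were assigned is not stated.

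The fitting code was tested on simulated data with 18419 genes at the estimated depths and a spread of 0.2 on the log2 scale. At 2 libraries per group it called 17 of 100 genes with a simulated 2-fold change and 79 of 100 with a 4-fold change. It made 105 calls in all, 9 of them false, and 3 calls in a comparison without simulated changes. A simulated list of 15 genes at 1.5-fold reached an adjusted p of 2.5e-07, and a list without change had a p of 0.49. Genes were simulated as independent, so these results do not cover lists of correlated genes. In the real lists the estimated correlation ran from -0.1 to 0.72.

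Other settings chosen before the data were examined were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, scaling by the median ratio, quantile normalization, no variance trend, the replicate number as a block, leaving out each library in turn, and fits of only the 4 libraries compared. Added after the values were seen were a filter at a mean of at least 10 estimated fragments (14135 genes), voom weights on estimated fragments of these genes, removal of the trend with transcript length in each library, log2 depth as a covariate, and camera tests on 238 process terms of 10 to 300 genes from the reference annotation. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 was used for depth estimates, exact permutation tests and figures.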

Results

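The data are FPKM values of endosperm transcripts from the 4 reciprocal cross combinations of Col-0 and ein2-5, a line with a loss-of-function allele of EIN2, the central transducer of the ethylene signal. The parent written before the x was taken as the mother, which the labels do not state: Col-0 x Col-0, Col-0 x ein2-5, ein2-5 x Col-0 and ein2-5 x ein2-5, with 2 libraries each. The study's title names EIN2, endosperm cellularization and seed size, and the comparisons ask how endosperm transcripts differ when the mother, the father or both carry ein2-5. Depth was estimated at 0.535 and 1.394 in Col-0 x Col-0, 1 and 1.136 in Col-0 x ein2-5, 0.973 and 0.886 in ein2-5 x Col-0, and 1.01 and 1.616 in ein2-5 x ein2-5, relative to Col-0 x ein2-5 replicate 1, a 3.02-fold range. Between 18170 and 20951 genes were above 0 per library.

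Replicates correlated at 0.937 to 0.957 across genes (Pearson r of log2 values), and libraries of different crosses at 0.922 to 0.961, so replicates of a cross were no closer to each other than to libraries of some other crosses. Col-0 x Col-0 replicate 1, the shallowest library, stood apart at -71.8 on the first principal component, which held 25.7% of the variance, while its partner was at -1.3. The ein2-5 x ein2-5 libraries lay at the other end, at 45.5 and 41.3. All group values below are FPKM means ± SD with n = 2, and log2 fold changes carry the standard error (SE) of the model.

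EIN2 (AT5G03280) was measured at 35.72 and 54.85 FPKM in the Col-0 x Col-0 libraries, 31.39 and 50.03 in Col-0 x ein2-5, 26.15 and 22.19 in ein2-5 x Col-0, and 19.66 and 23.66 in ein2-5 x ein2-5, with about 193 estimated fragments per library. The 4 libraries with a mutant mother were thus lower than the 4 with a wild-type mother. The maternal ein2-5 effect on EIN2 was -0.85 ± 0.20 (log2, SE), with an adjusted p of 0.69 over all genes and 0.049 over the ethylene perception and signalling list alone. The paternal effect was -0.15 (adjusted p = 0.89) and the interaction 0.00. ein2-5 x ein2-5 differed from Col-0 x Col-0 by -1.0 ± 0.28 (adjusted p = 0.35).

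**Figure D1:**
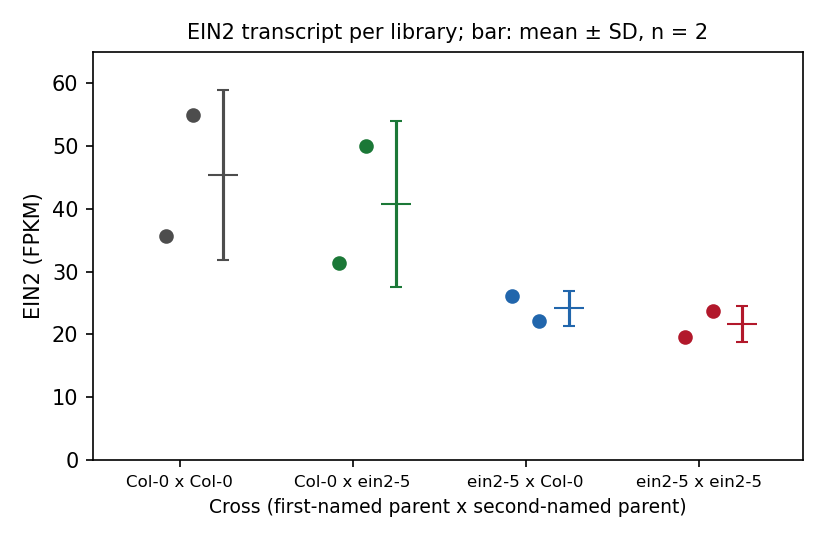
EIN2 transcript level in FPKM (vertical axis) in each library of the 4 crosses (points), with the mean ± SD of n = 2 beside them. The 4 libraries with an ein2-5 mother lie between 19.66 and 26.15, below the 4 with a Col-0 mother.

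Seed coat markers, mostly genes of the flavonoid and tannin pathway of the seed's outer layers, were the group with the clearest difference when both parents carried ein2-5. The list rose in ein2-5 x ein2-5 against Col-0 x Col-0, with a median log2 change of 1.04, 18 of 19 members higher and an adjusted p of 1.4e-08, against an adjusted p of 0.42 with an estimated correlation. TT4, the chalcone synthase that opens the flavonoid pathway and the most abundant member, measured 211 ± 63.7 and 357 ± 126 FPKM. Chosen after their values were seen, TT3 (dihydroflavonol reductase) measured 82.0 ± 5.61 and 169 ± 40.9, BAN (anthocyanidin reductase) 121 ± 8.25 and 211 ± 52.9, and LDOX (leucoanthocyanidin dioxygenase) 96.2 ± 3.02 and 204 ± 46.5. None passed over all genes, and 15 members passed when adjusted over the list alone, at adjusted p-values of 0.039 to 0.049. MUM4, a mucilage gene, was the exception at -0.25 ± 0.37. The list call held under each of 19 alternative settings other than the estimated correlation (adjusted p of 3e-10 to 3e-04).

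Type I MADS-box genes, transcription factors active in early endosperm, rose as a group, with a median of 1.06, 15 of 16 tested members higher and an adjusted p of 3.3e-05 (adjusted p = 0.42 with an estimated correlation). No member passed over all genes and 5 did when adjusted over the list alone: AGL28, AGL35, AGL40, AGL45 and PHE1. Of these, chosen after their values were seen, AGL28 measured 5.77 ± 0.168 and 34.8 ± 3.72, AGL35 47.3 ± 4.37 and 170 ± 36.8, and AGL40 54.8 ± 10.8 and 162 ± 40.8. AGL62, whose product holds back endosperm cellularization, measured 3.02 ± 0.561 and 15.7 ± 11.0 (log2 change 1.89 ± 0.72) and did not pass. AGL87, the most abundant member, hardly differed at 348 ± 93.3 and 360 ± 65.6. The ein2-5 x ein2-5 libraries scored 1.23 and 0.39 on this list and 0.90 and 0.47 on the seed coat list, against -0.35 and -0.56, and -0.50 and -0.29, in Col-0 x Col-0. The MADS-box call was lost without Col-0 x Col-0 replicate 2 (adjusted p = 0.087, the highest of 19 settings that ranged from 2.8e-08), and the median was 1.87 without ein2-5 x ein2-5 replicate 2.

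Endosperm markers rose with a median of 0.90, 9 of 11 members higher and an adjusted p of 0.0033 (adjusted p = 0.42 with an estimated correlation). Of the list's 15 genes, 9 also stand in other lists. No member passed over all genes and 4 passed when adjusted over the list alone: ESF1.2, FWA, PHE1 and MEA. PHE1, a paternally expressed imprinted MADS-box gene, measured 134 ± 55.9 and 245 ± 59.6. Chosen after their values were seen, ESF1.2, which encodes a small peptide of the embryo-surrounding endosperm, measured 81.8 ± 2.39 and 264 ± 60.7, FWA, a maternally expressed imprinted gene, 30.8 ± 3.59 and 62.7 ± 13.9, and MEA, a maternally expressed PRC2 subunit, 1.61 ± 0.16 and 9.06 ± 5.12. ZOU, a regulator of endosperm breakdown, was at 167 ± 40.8 and 143 ± 22.5. Seed coat markers were higher in the same libraries (median 1.04). The call was lost without Col-0 x Col-0 replicate 2 (adjusted p = 0.099) and without ein2-5 x ein2-5 replicate 1 (0.097), with 0.00037 to 0.099 over 19 settings.

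Seed storage proteins and oleosins, the coat proteins of oil bodies, fell with a median of -0.64, 6 of 7 tested members lower and an adjusted p of 0.0032 (adjusted p = 0.42 with an estimated correlation). No member passed over all genes, and OLEO2 and OLEO3 passed when adjusted over the list alone. OLEO3 measured 512 ± 82.1 in Col-0 x Col-0 and 327 ± 1.32 in ein2-5 x ein2-5, a log2 change of -0.64 ± 0.16. OLEO2 measured 37.5 ± 1.1 and 16.7 ± 2.13 (-1.12 ± 0.21). OLEO4, chosen after its values were seen, measured 22.0 ± 2.63 and 11.2 ± 0.224, while the albumin gene SESA1, chosen likewise, went the other way at 15.2 ± 3.15 and 34.6 ± 21.6. Seed coat markers moved in the opposite direction in the same libraries (median 1.04). The call was lost without ein2-5 x ein2-5 replicate 2 (adjusted p = 0.065, with 0.00061 to 0.065 over 19 settings).

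Cell cycle and cytokinesis genes fell slightly as a group, with a median of -0.11, 21 of 29 lower and an adjusted p of 0.003 (adjusted p = 0.42 with an estimated correlation). KNOLLE, the syntaxin of the cell plate, measured 535 ± 116 and 412 ± 59.3. No member passed over all genes or when adjusted over the list alone. The call was lost without Col-0 x Col-0 replicate 1 (adjusted p = 0.23), without ein2-5 x ein2-5 replicate 2 (0.067) and with depth as a covariate (0.15), with 0.00022 to 0.23 over 19 settings, and the median was -0.06 without Col-0 x Col-0 replicate 2, -0.22 after median-ratio scaling, -0.20 under quantile normalization and -0.24 with the transcript-length trend removed. Seed coat markers were higher in the same libraries (median 1.04).

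Photosynthesis genes had a median of -0.22, 18 of 21 lower and an adjusted p of 0.0033 (adjusted p = 0.70 with an estimated correlation), and 0 passed when adjusted over the list alone. CAB1, a chlorophyll-binding antenna protein, measured 1020 ± 495 and 743 ± 174. The difference was gone under quantile normalization (median 0.00, adjusted p = 0.91), and its direction turned without Col-0 x Col-0 replicate 1 (0.11, adjusted p = 0.26) and with depth as a covariate (0.05, adjusted p = 0.43). The median was -0.53 without Col-0 x Col-0 replicate 2, -0.37 without ein2-5 x ein2-5 replicate 1 and -0.06 without ein2-5 x ein2-5 replicate 2, and the call was lost in the last case (adjusted p = 0.79). Adjusted p-values spanned 4.1e-10 to 0.91 over 19 settings, and seed coat markers were higher in the same libraries (median 1.04).

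Ethylene perception and signalling genes, EIN2 among them, were lower relative to other genes with a median of -0.10, 8 of 16 lower and an adjusted p of 0.048 (adjusted p = 0.70 with an estimated correlation). RTE1, a regulator of the ETR1 receptor, measured 169 ± 16.8 and 142 ± 14.9. None passed over all genes or when adjusted over the list alone. The call was lost without Col-0 x Col-0 replicate 2 (median 0.02, adjusted p = 0.44), without ein2-5 x ein2-5 replicate 1 (-0.01, 0.21), and without either Col-0 x ein2-5 library (0.055 and 0.053), and also without a variance trend (0.062) and among genes with at least 10 fragments (median 0.05, adjusted p = 0.08), with 0.01 to 0.44 over 19 settings. The median was -0.23 without Col-0 x Col-0 replicate 1 and -0.21 without ein2-5 x ein2-5 replicate 2, and it ran from -0.23 to 0.05 over the 19 settings. Seed coat markers were higher in the same libraries (median 1.04).

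The other 12 lists were not called. Sugar transport and cleavage genes had a median of -0.56 (adjusted p = 0.059), with 1 of 6 past the threshold when adjusted over the list alone: SWEET15, a sugar exporter of the seed, at 260 ± 30.6 and 163 ± 35.7. SUC5, an endosperm sucrose carrier, measured 246 ± 69.1 and 265 ± 36.5. Imprinted genes and PRC2 had a median of 0.55 (0.059), with FWA alone past the threshold within the list, and HDG3, its most abundant member, at 261 ± 78.5 and 293 ± 89.5. Among abscisic acid genes (0.16, 0.93), 1 passed when adjusted over the list alone: NCED6, a biosynthesis enzyme of the endosperm, at 24.1 ± 0.852 and 46.7 ± 9.67. Among embryo markers (-0.20, 0.33) it was the epidermal regulator ATML1, at 11.7 ± 2.67 and 31.3 ± 1.44, while LEC1 measured 423 ± 42.5 and 367 ± 53.4. SWEET15, NCED6 and ATML1 were named after their values were seen. DNA replication genes were higher in 10 of 10 members (0.24, 0.27), with PCNA1 at 131 ± 39.9 and 148 ± 23.1.

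The remaining medians and adjusted p-values in this comparison were 0.18 and 0.93 for ethylene-responsive genes, 0.13 and 0.93 for ethylene biosynthesis, 0.14 and 0.93 for seed size regulators, 0.32 and 0.41 for auxin biosynthesis and Aux/IAA, 0.00 and 0.27 for DNA methylation and demethylation, 0.18 and 0.97 for defence and jasmonate response, and 0.17 and 0.97 for heat shock proteins. Within these 7 lists and DNA replication, 0 members passed when adjusted over the list alone. The signs of median, mean and test differed for ethylene-responsive genes, defence and heat shock (positive median and mean, test direction down) and for embryo markers (median -0.20, mean 0.05, direction down). EBF2, an F-box protein that targets EIN3, measured 44.6 ± 4.90 and 32.8 ± 6.90, and ARF2, a seed size repressor, 68.5 ± 17.5 and 60.2 ± 3.96. The most abundant members of other lists were also close: EOL1, a regulator of ethylene synthesis, with a log2 change of -0.02 ± 0.26 (SE), the abscisic acid enzyme ABA2 with -0.07 ± 0.15, the auxin response repressor IAA8 at 138 ± 9.47 and 111 ± 21.1 FPKM, and AGO4, of RNA-directed DNA methylation, at 88.6 ± 8.96 and 82.5 ± 5.52. The defensin PDF2.2 measured 1440 ± 737 and 923 ± 181, and the chaperone HSP90.1 46.4 ± 0.403 and 68.4 ± 0.587, neither of them called. The 7 lists called with the preset correlation became 0 with an estimated one. Leaving out 1 library added calls: imprinted genes and PRC2 without Col-0 x Col-0 replicate 1 (adjusted p = 0.0066), ein2-5 x Col-0 replicate 1 (0.033) or 2 (0.029), or ein2-5 x ein2-5 replicate 2 (0.01), DNA replication without Col-0 x Col-0 replicate 2 (0.043) or ein2-5 x ein2-5 replicate 2 (0.038), and sugar transport without ein2-5 x ein2-5 replicate 2 (0.035).

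**Figure D2:**
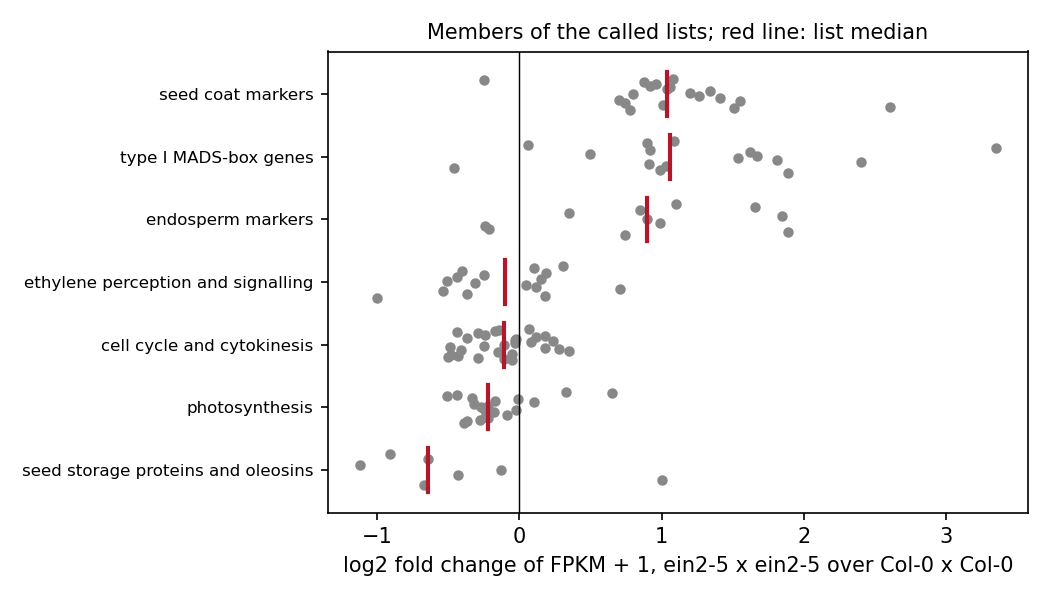
Log2 fold change of FPKM + 1 in ein2-5 x ein2-5 over Col-0 x Col-0 (horizontal axis) for each tested member (grey points) of the 7 called lists, with the list median in red. The seed coat median is 1.04, the storage protein and oleosin median -0.64, and the photosynthesis median of -0.22 becomes 0.00 under quantile normalization.

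Gene by gene, limma called 2 of 19719 genes in ein2-5 x ein2-5 against Col-0 x Col-0, both at an adjusted p of 0.034. AT1G69825, a defensin-like gene, was listed at 38.3 and 24.26 FPKM in ein2-5 x ein2-5 and at 0 in the other 6 libraries. AT4G36791, of unknown function, was listed at 109.3 and 41.95 FPKM in Col-0 x Col-0 and at 0 in the other 6. Both have short transcripts of 222 and 207 nt at the level that 1 fragment gives in other transcripts of such length (1.04 and 1.01 times it at most). Genes filled in by rank did not pass, among them SYTA, a membrane-trafficking synaptotagmin, at 123 ± 7.30, 92.3 ± 5.58, 78.1 ± 1.32 and 52.5 ± 4.23 in the 4 crosses in the order given above (ein2-5 x ein2-5 against Col-0 x Col-0: -1.22 ± 0.13, adjusted p = 0.083). SYTA was the 1 gene called with voom weights on fragments (-1.23, adjusted p = 0.021). The amino acid permease AAP8 was listed at 0 and 0.49 FPKM in Col-0 x Col-0 and at 12.94 and 12.34 in ein2-5 x ein2-5 (adjusted p = 0.23), the germin-like GLP5 23.1 ± 0.973 and 67.6 ± 1.52 (0.24), and the GTP cyclohydrolase AT3G07270 36.1 ± 4.46 and 89.2 ± 10.6 (0.24). The lipase AT1G71250 measured 401 ± 27.6 and 243 ± 15.4 (0.31).

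At an unadjusted p under 0.05 there were 2086 genes in this comparison, 1665 higher and 421 lower, where 986 are expected by chance, and 1768 with voom, where 707 are expected. The median of all genes was shifted by 0.12 in the deposited values and by 0.02 after median-ratio scaling. The count of 2 became 32 without Col-0 x Col-0 replicate 2, 8 without either ein2-5 x Col-0 library, 0 without either ein2-5 x ein2-5 library, and 0 among genes with at least 10 estimated fragments.

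With a mutant mother and a wild-type father, no gene group differed enough from Col-0 x Col-0 to be called. In ein2-5 x Col-0, OLEO3 measured 456 ± 52.4 against 512 ± 82.1 in Col-0 x Col-0, OLEO2, chosen after its values were seen, 55.3 ± 14.9 against 37.5 ± 1.1, PHE1 172 ± 9.16 against 134 ± 55.9, and TT4 242 ± 129 against 211 ± 63.7. Against Col-0 x Col-0, 0 of 19 lists were called in ein2-5 x Col-0. Ethylene perception and signalling came closest, with a median of -0.17 and 10 of 16 lower (adjusted p = 0.2), followed by storage proteins and oleosins with a median of 0.52 and 6 of 7 higher (0.28). EIN2 differed by -0.85 ± 0.28 (adjusted p = 1). The plant defensin PDF2.3, chosen after its values were seen, was the 1 gene past the threshold when adjusted over the list alone (defence and jasmonate response), at 14.4 ± 3.16 against 5.44 ± 0.542. For seed size regulators and DNA methylation the median, mean and test did not share a sign.

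The 2 ein2-5 x Col-0 libraries differed from each other on several lists: replicate 1 scored 0.16 on seed coat, 0.14 on MADS-box and 0.21 on endosperm markers, and replicate 2 scored -0.47, -0.41 and -0.59. Without replicate 2, 6 lists were called, among them seed coat markers (median 0.60, adjusted p = 0.00054), type I MADS-box genes (0.62, 0.01) and storage proteins and oleosins (0.80, 0.021). Without Col-0 x Col-0 replicate 1, 4 were called, with photosynthesis up (0.34, 1.4e-08), and without Col-0 x Col-0 replicate 2 photosynthesis alone was called, downwards (-0.27, 0.00072).

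No gene was called by limma in ein2-5 x Col-0 against Col-0 x Col-0, and none by voom. At an unadjusted p under 0.05 there were 789 genes by limma, against 986 expected, and 479 by voom, against 707. Among those ranked highest, none of which passed, PC1 (AT5G17480), a pollen calcium-binding protein, was listed at 0 in both ein2-5 x Col-0 libraries and at 39.61 and 15.2 in Col-0 x Col-0 (adjusted p = 0.087). Its values in the 6 libraries above 0 were equal once divided by depth (highest over lowest 1.009), as 1 fragment in each would give. The estimate from its length, about 5 fragments per library over all 8, may thus be too high. The unknown protein AT3G28990 measured 209 ± 58.0 against 66.4 ± 1.09 (0.84). The count became 11 without Col-0 x Col-0 replicate 2, 2 without Col-0 x Col-0 replicate 1, 4 without ein2-5 x Col-0 replicate 2, and 1 without either Col-0 x ein2-5 library.

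With a wild-type mother and a mutant father, photosynthesis genes fell as a group against Col-0 x Col-0, with a median of -0.15, 18 of 21 lower and an adjusted p of 0.015 (adjusted p = 0.97 with an estimated correlation). CAB1 measured 807 ± 77.3 in Col-0 x ein2-5 and 1020 ± 495 in Col-0 x Col-0, and 0 members passed when adjusted over the list alone. The direction turned without Col-0 x Col-0 replicate 1 (median 0.14, adjusted p = 0.052), and the call was lost without Col-0 x ein2-5 replicate 2 (-0.04, 0.47), with depth as a covariate (-0.02, 0.61), under quantile normalization (-0.04, 0.33), without a variance trend (0.059) and with the transcript-length trend removed (0.075). The median was -0.43 without Col-0 x Col-0 replicate 2 and -0.25 without Col-0 x ein2-5 replicate 1, and adjusted p-values spanned 2.1e-11 to 0.61 over 19 settings.

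The other 18 lists were not called in Col-0 x ein2-5 against Col-0 x Col-0, with adjusted p-values of 0.077 (cell cycle and cytokinesis, median -0.11) and above. Seed coat markers had a median of 0.23 with 16 of 19 higher (0.36), and type I MADS-box genes a median of 0.21 (0.95). OLEO3 measured 413 ± 0.613 against 512 ± 82.1, and EIN2 differed by -0.16 ± 0.28. Median, mean and test did not share a sign for ethylene perception, DNA replication, defence, storage proteins and sugar transport. No gene was called by limma or by voom, with 575 genes at an unadjusted p under 0.05 by limma (986 expected) and 325 by voom (707 expected). Among the genes ranked highest, AT2G35736, an uncharacterized gene, measured 405 ± 44.6 against 21.2 ± 7.46 (log2 change 4.23 ± 0.56, adjusted p = 0.71). It was also at 268 ± 33.0 in ein2-5 x ein2-5 and at 161 ± 138 in ein2-5 x Col-0. The oligosaccharyltransferase gene AT5G02502 measured 63.5 ± 5.72 against 95.9 ± 1.58. Without Col-0 x Col-0 replicate 2, cell cycle genes were called as a further list (adjusted p = 0.0071), and without Col-0 x ein2-5 replicate 2 heat shock proteins were (median 0.95, 9.2e-05). The gene count of 0 became 15 without Col-0 x Col-0 replicate 2, 2 without Col-0 x ein2-5 replicate 2, and 1 without Col-0 x Col-0 replicate 1 or either ein2-5 x Col-0 library.

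Between the reciprocal crosses, which ask whether the parent that transmits ein2-5 matters, photosynthesis and storage genes were higher with the mutant mother. The parent of origin is not separated here from the number of mutant copies in the endosperm or from the genotype of the mother's tissues. The averaged parental effects share this limit. Photosynthesis genes rose in ein2-5 x Col-0 against Col-0 x ein2-5, with a median of 0.21, 21 of 21 higher and an adjusted p of 3e-04 (adjusted p = 0.98 with an estimated correlation). CAB1 measured 948 ± 15.5 against 807 ± 77.3, and RBCS1A, a RuBisCO small subunit gene chosen after its values were seen, 681 ± 1.61 against 572 ± 42.6. The call was lost without Col-0 x ein2-5 replicate 2 (median 0.10, adjusted p = 0.1) and without ein2-5 x Col-0 replicate 1 (0.15, 0.1), with 2.1e-06 to 0.1 over 19 settings. The median was 0.33 without Col-0 x ein2-5 replicate 1, 0.12 under quantile normalization (adjusted p = 0.0026) and 0.11 with depth as a covariate (0.00046).

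Seed storage proteins and oleosins rose in ein2-5 x Col-0 against Col-0 x ein2-5, with a median of 0.51, 7 of 7 higher and an adjusted p of 0.0068 (adjusted p = 0.48 with an estimated correlation). OLEO1 measured 27.3 ± 3.74 against 15.1 ± 7.79 and OLEO2 55.3 ± 14.9 against 36.6 ± 0.752, both chosen after their values were seen, and OLEO3 456 ± 52.4 against 413 ± 0.613. In this comparison 0 members of any list passed when adjusted over the list alone. The storage call was lost without ein2-5 x Col-0 replicate 1 (median 0.26, adjusted p = 0.16, with 0.0015 to 0.16 over 19 settings), and the median was 0.86 without ein2-5 x Col-0 replicate 2.

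The other 17 lists were not called between the reciprocal crosses, and the lowest adjusted p among them was 0.098 (defence and jasmonate response, median 0.31). Seed coat markers had a median of 0.00 with 9 of 19 higher. EIN2 differed by -0.70 ± 0.28. ABA4, an abscisic acid biosynthesis gene, measured 10 ± 0.92 with the mutant mother against 21.9 ± 0.0938 (-1.06 ± 0.20), and the metal-binding protein HIPP22 17.9 ± 1.65 against 3.49 ± 0.315 (2.07 ± 0.41), each with an adjusted p of 1. PC1 was listed at 0 with the mutant mother and at 21.01 and 18.5 with the mutant father (adjusted p = 0.28). Its values above 0 were equal once divided by depth (highest over lowest 1.009 in 6 libraries), as 1 fragment in each would give. Median, mean and test did not share a sign for seed size regulators, abscisic acid and sugar transport. No gene was called by limma or by voom, with 595 genes at an unadjusted p under 0.05 by limma (986 expected) and 439 by voom (707 expected). The count of 0 became 5 without ein2-5 x Col-0 replicate 2, 4 without Col-0 x ein2-5 replicate 2, and 2 without either Col-0 x Col-0 library. The list count of 2 became 5 without ein2-5 x Col-0 replicate 2, when seed coat markers were higher (median 0.37, adjusted p = 0.01), and 5 without Col-0 x ein2-5 replicate 1, when heat shock proteins were higher (0.8, 0.023). Without ein2-5 x Col-0 replicate 1 seed coat markers were lower (-0.38, 0.021), and without Col-0 x ein2-5 replicate 2 heat shock proteins were (-0.54, 0.00045).

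Averaged over fathers, the maternal ein2-5 effect called 4 lists. Seed coat markers rose with a median of 0.49 (18 of 19 higher, adjusted p = 7.5e-06), type I MADS-box genes with 0.71 (15 of 16, 2.1e-05) and endosperm markers with 0.43 (8 of 11, 0.034), and ethylene perception and signalling genes fell with -0.11 (10 of 16 lower, 0.015), all at an adjusted p = 0.73 with an estimated correlation. ESF1.2 (0.83) and EIN2 (-0.85) passed when adjusted over the list alone. EIN2, the mutated gene, was the lowest member of the ethylene list, which was not tested without it. The endosperm call was lost under 8 of 19 settings (adjusted p of 0.0014 to 0.37), among them without Col-0 x Col-0 replicate 2 (0.16), Col-0 x ein2-5 replicate 2 (0.067), ein2-5 x Col-0 replicate 1 (0.37) and ein2-5 x ein2-5 replicate 1 (0.28), and its median was 0.68 without Col-0 x ein2-5 replicate 1 and 0.67 without ein2-5 x Col-0 replicate 2. The ethylene call was lost without Col-0 x Col-0 replicate 2 (0.12), without Col-0 x ein2-5 replicate 2 (0.069) and among genes with at least 10 fragments (0.054), with 0.0044 to 0.12 over 19 settings. Without ein2-5 x Col-0 replicate 1 the seed coat median was 0.30 and the MADS-box median 0.47, and both calls held. Without Col-0 x ein2-5 replicate 2, 2 lists were called, and without Col-0 x Col-0 replicate 1 photosynthesis genes were called upwards (median 0.15, 0.00055) and without Col-0 x Col-0 replicate 2 downwards (-0.16, 0.0018), against -0.01 with all libraries.

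Averaged over mothers, the paternal effect called 6 lists. Seed coat markers rose with 0.52 (18 of 19 higher, adjusted p = 1.3e-06), type I MADS-box genes with 0.57 (12 of 16, 0.0067) and endosperm markers with 0.41 (9 of 11, 0.0067), while photosynthesis genes fell with -0.22 (19 of 21 lower, 1.3e-06) and cell cycle genes with -0.06 (21 of 29, 0.0027), all at an adjusted p = 0.59 with an estimated correlation. Storage proteins and oleosins fell with -0.51 (6 of 7 lower, 2.2e-05, and adjusted p = 0.17 with an estimated correlation). With a Col-0 mother this list did not fall as a group. In Col-0 x ein2-5 against Col-0 x Col-0 its median was 0, with 3 members higher and 4 lower (adjusted p = 0.61). OLEO2 (-0.84), OLEO3 (-0.39) and ESF1.2 (0.83) passed when adjusted over the list alone. The storage call held under each of the 19 other settings (1.5e-06 to 0.0024), as did the seed coat call (7.7e-10 to 0.0013), whose median was 0.33 without ein2-5 x Col-0 replicate 2.

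The other paternal calls depended on single libraries, and the MADS-box call was also lost among genes with at least 10 estimated fragments. The MADS-box call was lost without Col-0 x Col-0 replicate 2 (adjusted p = 0.49), Col-0 x ein2-5 replicate 1 (0.17) or ein2-5 x ein2-5 replicate 1 (median 0.33, 0.45), with 2.9e-06 to 0.49 over 19 settings, and its median was 0.90 without ein2-5 x ein2-5 replicate 2. The endosperm call was lost without Col-0 x Col-0 replicate 2 (0.17), ein2-5 x Col-0 replicate 2 (median 0.24, 0.053) or ein2-5 x ein2-5 replicate 1 (0.2), with 0.00037 to 0.2. The cell cycle call was lost without Col-0 x Col-0 replicate 1 (0.13), without ein2-5 x Col-0 replicate 2 (median 0.01, 0.13) and with depth as a covariate (0.21), with 6.4e-05 to 0.21, and its median was -0.11 without ein2-5 x Col-0 replicate 1 and -0.17 under quantile normalization. The photosynthesis call was lost without Col-0 x Col-0 replicate 1 (median -0.05, 0.14), with depth as a covariate (-0.03, 0.23) and under quantile normalization (-0.04, 0.055), with 3.8e-14 to 0.23. Its median was -0.37 without Col-0 x Col-0 replicate 2, -0.14 without Col-0 x ein2-5 replicate 2 and -0.13 without ein2-5 x ein2-5 replicate 2.

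The interaction, which asks whether a mutant father changes more with a mutant mother than with a wild-type one, called 3 lists. Storage proteins and oleosins had a median of -1.01 with 6 of 7 lower (adjusted p = 0.00049, and adjusted p = 0.27 with an estimated correlation): OLEO2 measured 37.5 ± 1.1, 36.6 ± 0.752, 55.3 ± 14.9 and 16.7 ± 2.13 in the 4 crosses in the order given above, and it passed when adjusted over the list alone. Seed coat markers had a median of 0.54 with 17 of 19 higher (0.00049) and type I MADS-box genes 0.57 with 11 of 16 higher (0.013), both at an adjusted p = 0.87 with an estimated correlation. The storage call held under each of the 19 other settings (5.9e-05 to 0.019). The seed coat call was lost without ein2-5 x Col-0 replicate 2 (median 0.22, 0.074) or ein2-5 x ein2-5 replicate 1 (0.36, 0.18), with 1.4e-07 to 0.18, and its median was 0.88 without ein2-5 x Col-0 replicate 1 and 0.87 without ein2-5 x ein2-5 replicate 2. The MADS-box call was lost without Col-0 x Col-0 replicate 1 (0.68), Col-0 x ein2-5 replicate 2 (median 0.30, 0.2), ein2-5 x Col-0 replicate 2 (0.074) or ein2-5 x ein2-5 replicate 1 (median 0.27, 0.7), and with voom weights (0.30, 0.3), with 5.1e-05 to 0.7, and its median was 0.97 without Col-0 x Col-0 replicate 2. The count of 3 lists became 5 without Col-0 x Col-0 replicate 2, with photosynthesis genes up (0.19, 0.022), 5 without Col-0 x ein2-5 replicate 1 or ein2-5 x Col-0 replicate 1, 6 without ein2-5 x ein2-5 replicate 2, and 1 without ein2-5 x Col-0 replicate 2. Photosynthesis genes were called downwards without Col-0 x Col-0 replicate 1 (-0.39, 1.3e-07), ein2-5 x ein2-5 replicate 1 (-0.27, 8e-04) or Col-0 x ein2-5 replicate 2 (-0.20, 0.042).

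No gene was called by limma or by voom for these 3 contrasts. At an unadjusted p under 0.05, limma gave 1397 genes for the maternal effect, 1199 for the paternal effect and 662 for the interaction, against 986 expected, and voom gave 1217, 1044 and 447, against 707. Without Col-0 x Col-0 replicate 2, limma called 12 genes for the maternal effect, 10 for the paternal effect and 2 for the interaction. Without ein2-5 x Col-0 replicate 2 these counts were 6, 1 and 3, and without Col-0 x Col-0 replicate 1 they were 2, 1 and 3. Without Col-0 x ein2-5 replicate 1 they were 1, 1 and 3. Col-0 x ein2-5 replicate 2 gave 2 paternal calls when left out, ein2-5 x Col-0 replicate 1 gave 1 maternal call, and ein2-5 x ein2-5 replicate 1 gave 1 paternal call.

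**Figure D3:**
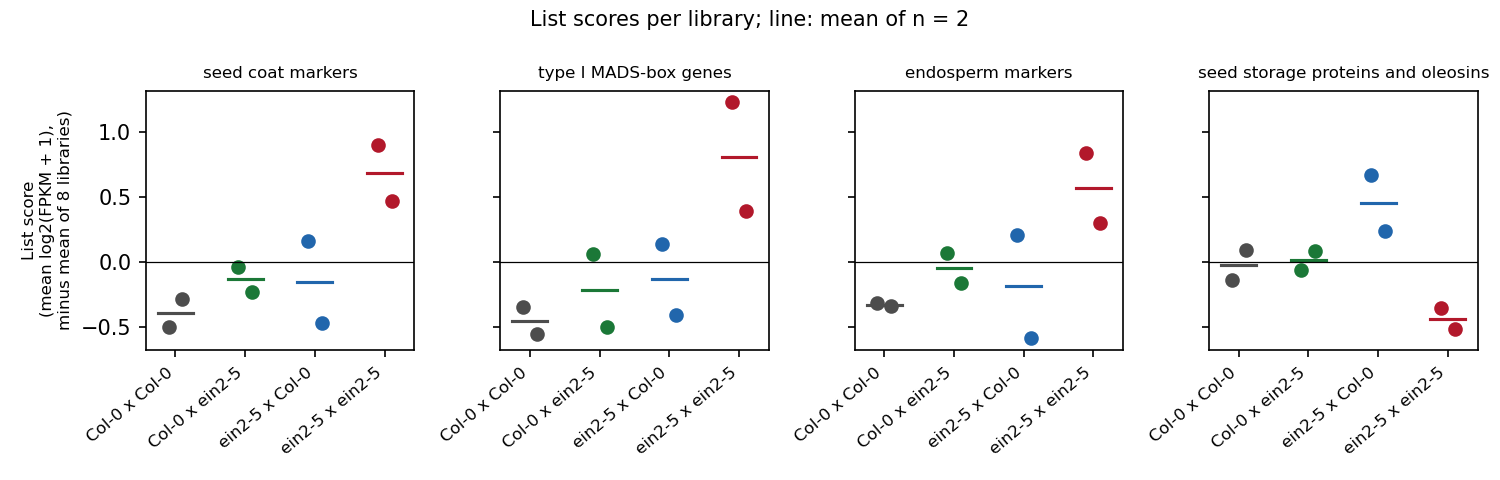
List scores (mean log2(FPKM + 1) of the members, minus the mean of the 8 libraries) per library (points) and per cross (lines, n = 2) for 4 lists. The ein2-5 x ein2-5 libraries score 0.90 and 0.47 on the seed coat list and -0.36 and -0.52 on the storage protein and oleosin list.

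Photosynthesis genes tracked sequencing depth. Their list score correlated with log2 depth over the 8 libraries (Pearson r = -0.88, exact permutation p = 0.001, adjusted p = 0.019 over the 19 lists, and Spearman rho = -0.93, p = 0.0022, adjusted p = 0.042, both two-sided). Without the 2 libraries farthest from the median depth, Col-0 x Col-0 replicate 1 and ein2-5 x ein2-5 replicate 2, r was -0.79 over 6 libraries. Within crosses, the shallower library had the higher score in 3 of 4, as it also had for 5 other lists. None of the other 18 lists passed. The next by r were ethylene biosynthesis (r = 0.75, rho = 0.57, adjusted p = 0.272 and 0.456) and DNA methylation (r = 0.74, rho = 0.52, 0.272 and 0.456), and the next by rho was ethylene perception and signalling (rho = 0.60, r = 0.61, 0.456 and 0.403), whose r without those 2 libraries was 0.87. Seed coat markers had r = 0.42 and rho = 0.52 (0.715 and 0.456), and -0.17 without those 2 libraries.

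**Figure D4:**
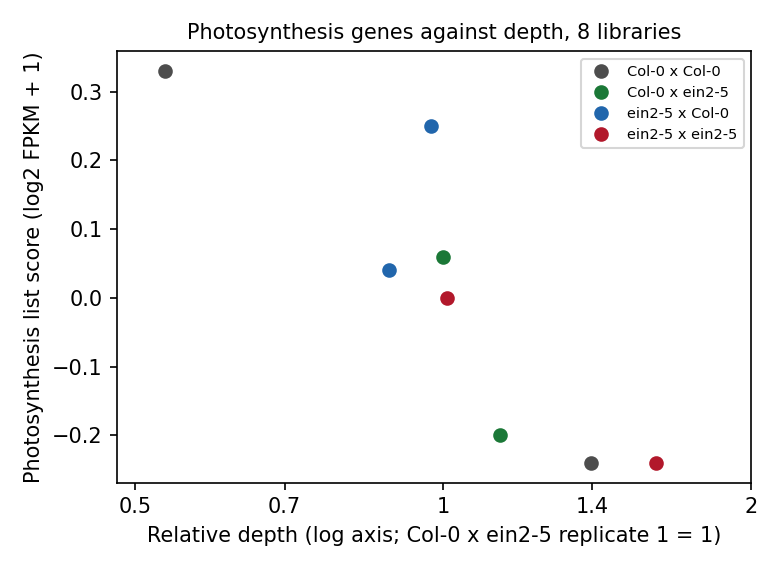
Photosynthesis list score (vertical axis, log2 scale) against relative sequencing depth (horizontal axis, logarithmic, with Col-0 x ein2-5 replicate 1 at 1) for the 8 libraries, coloured by cross. The score falls with depth, with r = -0.88.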

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

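The interaction tests, the estimated correlation, the fits without 1 library and the test of genes found in 2 libraries were chosen before their results were seen, and the other tests of explanations, the depth covariate, the length trend and the splits after. The following 3 gene groups are given here because the effect of a mutant father differed between a Col-0 and an ein2-5 mother in a test of the interaction: storage proteins and oleosins (median -1.01, adjusted p = 0.00049), seed coat markers (0.54, 0.00049) and type I MADS-box genes (0.57, 0.013). With an estimated correlation the adjusted p-values were 0.27, 0.87 and 0.87, and over 19 other settings they spanned 5.9e-05 to 0.019, 1.4e-07 to 0.18 and 5.1e-05 to 0.7. OLEO2 carried the pattern most clearly, at 55.3 ± 14.9 FPKM in ein2-5 x Col-0 and 16.7 ± 2.13 in ein2-5 x ein2-5. Without ein2-5 x Col-0 replicate 2 the medians of seed coat and MADS-box genes were 0.22 and 0.41, and without ein2-5 x ein2-5 replicate 1 they were 0.36 and 0.27, with all 4 calls lost. The MADS-box call was also lost without Col-0 x Col-0 replicate 1 (0.58, adjusted p = 0.68) and Col-0 x ein2-5 replicate 2 (0.30, 0.2).

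The higher seed coat and type I MADS-box genes in ein2-5 x ein2-5 (medians 1.04 and 1.06 against Col-0 x Col-0) were weighed first. The shallow library Col-0 x Col-0 replicate 1 is argued against as their cause, since without it both lists were still called (adjusted p = 3.4e-07 for each, within 3e-10 to 3e-04 and 2.8e-08 to 0.087 over 19 settings), although with all libraries both had an adjusted p = 0.42 with an estimated correlation. For the seed coat markers, seed coat tissue among the captured cells and regulation of the same genes cannot be told apart: 92.3% of the 13 markers with at least 10 fragments lay within 2 SE of a common change of 0.96, but so did 85.1% of all such genes around their own median, and 5 of the 18 other lists reached as high a share. Such tissue would lower rather than raise the endosperm's own MADS-box genes, whose median was 1.06. A younger endosperm on the same day may explain the MADS-box genes and goes with the lower storage proteins and oleosins (median -0.64). The latter do not single out age, since seed coat tissue among the captured cells could lower them too. An effect of ein2-5 in both parents on seed coat or endosperm transcripts stays open as well. These data do not separate it from a difference in age or in the cells captured. The seed coat is the mother's tissue, so a father's allele could act on it only indirectly. Its markers had a median of 0.52 for the paternal effect and 0.49 for the maternal effect, but both averages include ein2-5 x ein2-5. Against Col-0 x Col-0 the list was not called in Col-0 x ein2-5 (median 0.23, adjusted p = 0.36) or ein2-5 x Col-0 (0.2, adjusted p = 0.57). The near-equal averages thus do not tell whether a father's allele acted on the seed coat.

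The 2 genes called between ein2-5 x ein2-5 and Col-0 x Col-0, AT1G69825 and AT4G36791, may rest on single sampled fragments. In both of the 2 genes the values above 0 were equal within 6% once divided by depth, and they stood at 1.02 to 1.04 and at 1.01 times the level of 1 fragment, read from the smallest values of 11 and 10 other genes within 10 nt of their lengths. Expression limited to 1 cross is argued against for such genes as a class: 86 of 625 genes found in exactly 2 libraries at depth-corrected values equal within 6% fell in the 2 libraries of 1 cross, where depth alone gives 86.5, a ratio of 0.99. That class result does not exclude it for the 2 genes themselves.

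Photosynthesis genes were higher in ein2-5 x Col-0 than in Col-0 x ein2-5 (median 0.21, adjusted p = 3e-04, and 2.1e-06 to 0.1 over 19 settings, but adjusted p = 0.98 with an estimated correlation). Depth may account for a part of this, since the median was 0.11 with log2 depth as a covariate. Whether it is the whole cause cannot be told. The list was still called (adjusted p = 0.00046), but with the preset correlation of 0.01, while the data gave an estimate of 0.69. With the trend in transcript length removed the median was still 0.21. This unchanged median argues against that trend as the whole cause, while its adjusted p of 0.014 rests on the same preset correlation. The call was lost without Col-0 x ein2-5 replicate 2 (0.10, adjusted p = 0.1) and without ein2-5 x Col-0 replicate 1 (0.15, 0.1). An effect of the parent that carried ein2-5 stays open, untested beyond the comparison itself. Parent of origin, the number of mutant copies in the endosperm and the mother's genotype are not separated.

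Chance cannot be excluded for the number of genes that differed by mother or by father. When the 8 libraries were split into 4 and 4 by mother, 1320 genes had an unadjusted p under 0.05, and 9 of the 35 possible splits gave as many, the highest other giving 2124. By father there were 1091 genes, and 10 of 35 splits gave as many, with the same highest split. That split sets the 4 shallowest libraries against the 4 deepest, but it also puts both ein2-5 x Col-0 libraries and Col-0 x Col-0 replicate 1 on one side, so depth was not separated from these as its source.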

How the results depend on the processing

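Chosen after the values were seen were the filter at 10 fragments, voom, the length trend and the depth covariate. Of 3335 values for genes under other settings, 3293 were counted as unchanged, 16 fell below the threshold, 26 passed it and 0 turned. Of 2660 for lists, the numbers were 2492, 76, 82 and 10. A turn was counted only where the value was called in the main fit or under the other setting. A change of direction without a call was counted as unchanged, so these counts do not show that uncalled values kept direction. For genes in ein2-5 x ein2-5 against Col-0 x Col-0, the count of 2 became 0 with a pseudocount of 0.1, a filter at 5 FPKM, a filter at 10 fragments (fewer genes tested, without the 2 called) and the depth covariate, 1 with voom, 4 with median-ratio scaling, 11 with no variance trend and 8 with only the 4 libraries compared. For ein2-5 x Col-0 against Col-0 x Col-0, 0 became 1 with the pseudocount, 3 with no variance trend, 1 with the length trend removed and 2 with the depth covariate. For Col-0 x ein2-5 against Col-0 x Col-0 it became 1 with no variance trend and 1 with the length trend removed. Between the reciprocal crosses it became 1 with the pseudocount, 4 with no variance trend, 1 with the depth covariate and 3 with only the 4 libraries compared, and for the maternal effect 1 with no variance trend. Leaving out 1 library at a time, with the lone library of a cross assumed to vary like the others, gave 0 to 32, 0 to 11, 0 to 15 and 0 to 5 genes in these 4 comparisons in that order, 0 to 12 for the maternal effect, 0 to 10 for the paternal effect and 0 to 3 for the interaction. The cause was not tested.

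Lists depended most on the correlation between genes: with an estimated one, 0 were called in each of the 7 contrasts. The 1 list called in Col-0 x ein2-5 against Col-0 x Col-0 became 2 with median-ratio scaling and with the filter at 10 fragments, and 0 with quantile normalization, no variance trend, the length trend removed and the depth covariate. In ein2-5 x Col-0 against Col-0 x Col-0, 0 became 3 with the depth covariate. Leaving out 1 library gave 0 to 2 and 0 to 6 lists in these 2 comparisons, 2 to 5 between the reciprocal crosses, 2 to 6 for the maternal effect and 1 to 6 for the interaction. By the direction of the test, photosynthesis genes turned in ein2-5 x ein2-5 against Col-0 x Col-0 under quantile normalization, where the difference was gone (median 0), with the depth covariate (0.05), and for the maternal effect with the depth covariate (0.08). With 1 library left out their median ranged from -0.53 to 0.11 in ein2-5 x ein2-5, -0.43 to 0.14 in Col-0 x ein2-5 and -0.27 to 0.34 in ein2-5 x Col-0, each against Col-0 x Col-0, from -0.16 to 0.15 for the maternal effect and from -0.39 to 0.19 for the interaction, and turned without a Col-0 x Col-0 library in each case. Between the reciprocal crosses, heat shock proteins ranged from -0.54 to 0.8, turning without Col-0 x ein2-5 replicate 1, and seed coat markers from -0.38 to 0.37, turning without ein2-5 x Col-0 replicate 2. The cause was not tested.

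Replicate numbers were also tried as a block, although nothing states that they pair libraries: replicate differences correlated at only 0.14, 0.01, 0.09, 0.05, 0.05 and 0.04 between crosses. With the replicate block, the count of genes in ein2-5 x ein2-5 against Col-0 x Col-0 became 0. The number of lists called went from 7 to 8 in that comparison, from 6 to 7 for the paternal effect and from 3 to 5 for the interaction. Depth limits what can be seen: 1 fragment on a transcript of 0.6 kb stands for 1.99 to 6.02 FPKM.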

Other observations

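All tests in this part were chosen after the values were seen. Among 238 process terms, 9 were called in ein2-5 x ein2-5 against Col-0 x Col-0, and 0 with an estimated correlation. Fatty acid biosynthesis genes fell, with 34 of 45 lower, a median of -0.15 and an adjusted p of 0.00048 (-0.09 and 0.01 with depth as a covariate), next to the lower oleosins and while seed coat markers were higher in the same libraries (median 1.04). The plastid acyl carrier protein ACP5 measured 279 ± 7.46 and 210 ± 8.13, the ketoacyl synthase KASI 462 ± 70.1 and 368 ± 32.6, and the pyruvate kinase PKP-BETA1 272 ± 0.387 and 216 ± 24.1, while other members went the other way, such as the acyl-CoA synthetase LACS1 at 11.5 ± 2.65 and 23.1 ± 2.41 and the ketoacyl synthase AT2G04540 at 7.15 ± 5.15 and 15.7 ± 1.97. Ovule development genes were higher in 17 of 20 (0.5, adjusted p = 0.038, and 0.074 with the depth covariate), again with the seed coat markers higher. Fatty acid biosynthesis genes were also lower in Col-0 x ein2-5 than in Col-0 x Col-0 (median -0.11, adjusted p = 0.0021). There, storage proteins and oleosins had a median of 0. Fatty acid biosynthesis genes were higher in ein2-5 x Col-0 than in Col-0 x ein2-5 (0.11, adjusted p = 0.032), but not called with the transcript-length trend removed (adjusted p = 0.074). Neither call held with an estimated correlation.

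Ribosome biogenesis genes were higher in ein2-5 x Col-0 than in Col-0 x ein2-5, in 93 of 101 genes (median 0.18, adjusted p = 2.9e-10, and 0.11 and 2.2e-12 with depth as a covariate, but adjusted p = 1 with an estimated correlation). They were lower in Col-0 x ein2-5 than in Col-0 x Col-0 (-0.13, 7e-04), where the covariate left a median of -0.01 (adjusted p = 0.78), and in ein2-5 x ein2-5 than in Col-0 x Col-0 (-0.11, 0.024), where it left 0.05 (0.27). Both also had an adjusted p of 1 with an estimated correlation. In ein2-5 x Col-0 against Col-0 x Col-0 they were not called (0.07, 0.4), but were with the covariate (0.1, 3.5e-06), and the adjusted p was 1 with an estimated correlation and no covariate.

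Heat shock proteins differed widely between replicates. Their list scores were 0.04 and -0.31 in Col-0 x Col-0, 0.83 and -0.53 in Col-0 x ein2-5, 0.50 and -0.52 in ein2-5 x Col-0, and -0.50 and 0.49 in ein2-5 x ein2-5. The small heat shock protein HSP17.6II measured 36.6 and 4.6 FPKM in the Col-0 x ein2-5 libraries, 25.1 and 3.9 in ein2-5 x Col-0, and 5.2 and 24.8 in ein2-5 x ein2-5.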
